A study of Tuber magnatum and Quercus robur
Tuber magnatum with 9 samples.

How the data were processed

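Messenger RNA of the white truffle Tuber magnatum, an ascomycete that lives in ectomycorrhizal symbiosis with tree roots, was sequenced from 3 tissues with 3 libraries each. Free-living mycelium was a liquid culture of an isolate from a single fruiting body, grown for 30 days. Fruiting bodies were 3 separate field truffles; number 1 was collected in 2005 at one locality, and numbers 2 and 3 were collected in 2006 at another. Ectomycorrhizal root tips, in which fungal hyphae ensheath the fine roots, came from 6-month-old inoculated pedunculate oaks. Per the labels' protocols, paired reads were produced on an Illumina HiSeq2000. RNA of mycelium and fruiting bodies was extracted with one kit and RNA of the root tips with another, so kit and tissue coincide for the root tips. The labels call the 3 replicates of each tissue biological; whether the mycelium libraries came from separate cultures is not given in the sources used here, and p-values against mycelium may measure a spread that is partly technical.

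The deposited files give, for each library, 2 columns of read counts per gene and an RPKM value. Per the file headers, the first count column holds the reads that matched a single gene and the second holds all gene reads. The aligner, the counting tool, the genome build, the strand setting and the treatment of oak reads in the root tip libraries are not given in the sources used here. The RPKM values of the authors were checked against the counts: total reads divided by RPKM and by the column total gave a whole-number length for each of the 9342 genes with a read, the same in all libraries to within 0.00025 nt. RPKM was therefore scaled to the sum of gene reads of each library, and it was used here only to recover these gene model lengths, which ran from 150 to 14815 nt. Lengths were multiples of 3 for 65.5% of genes.

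Each file lists the same 9433 genes by JGI protein ID, of which 91 had no read in any library. The files do not pair the IDs with names or products, and no genome or annotation was used here. The 36 gene lists fixed beforehand were to be matched on products and protein sequences, so none of them was tested and no gene function is given. Gene positions are not given for the same reason. No row lacked a gene ID.

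Total gene reads were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings, which kept 8695 genes and left out 738. The genes kept held at least 99.9% of the reads of every library. Libraries were scaled by TMM, the trimmed mean of log ratios. A quasi-likelihood model with robust settings was fitted to all 9 libraries, with tissue as the only term, and the 3 pairwise contrasts were tested two-sided with glmQLFTest. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Genes called with an estimated change of at least 4-fold were counted separately. Genes were counted as enriched in a tissue when they were called at least 4-fold higher than in both other tissues. Levels are CPM, gene reads scaled to the TMM-adjusted library size, given as mean ± SD of 3 libraries. Standard errors of log2 fold changes are the estimate divided by the square root of the quasi-likelihood F.

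Genes named in the comparisons follow a rule fixed before the data were examined: among called genes with a mean of at least 10 CPM over the 9 libraries and no overlap between the libraries of the 2 tissues, the 2 with the largest estimated change in each direction. The other parts of that rule needed product names and could not be applied. The genes with the largest share of reads were singled out after their values were seen. Where a tissue had no read of a gene, the fold is a lower bound against 3 reads summed over its 3 libraries. Such bounds, like all counting limits here, cover counting error only, since sequenced reads without molecular identifiers are not independent molecules.

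Total gene reads ranged from 38378805 to 65107611 in mycelium and fruiting bodies and from 5441312 to 9082794 in root tips, so low levels were measured less precisely in root tips. Between 98.9% and 99.4% of reads matched a single gene. For 404 genes under 90% of reads were unique, and their counts are uncertain because the authors' counting could split reads between near-identical copies.

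The test was tried on simulated counts with 200 genes changed. Counts were drawn from the average level of the 2 tissues compared, with the real library sizes and dispersions. For root tips against mycelium, 64 of 100 genes changed 4-fold and 6 of 100 changed 2-fold were recovered, with 3 false calls among 73, over 8144 genes. For fruiting body against mycelium 67 and 2 of 100 were recovered over 8673 genes, and for root tips against fruiting body 52 and 8 of 100 over 8630 genes. Far more genes were called in the real data (3952 to 5258), and the adjusted p cut is stricter when few genes change. These recoveries therefore do not give the power of the real test and may understate it. A missing call still does not show that a gene kept its level.

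Alternatives listed before the data were examined were the DESeq2 1.42.0 Wald test, median-of-ratios scaling, scaling by library totals, no filter and a stricter filter, fits of only the 2 tissues compared, the replicate number as a block, binomial thinning of all libraries to the smallest total, removal of the 20 most abundant genes, and leaving out each library. Alternatives added after the data were seen were unique reads, mycelium libraries 1 and 2 summed as 1 library because their descriptions share a number, and removal of each library's smooth trend with gene length. Comparisons sharing a tissue were set beside 20 simulated data sets without any difference between tissues.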

Results

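The 9 libraries profiled the truffle fungus in 3 states: mycelium growing alone in culture, mycelium in symbiosis with oak roots, and the fruiting body. Total gene reads per library ran from 38378805 to 56461454 in mycelium, from 59108330 to 65107611 in fruiting bodies and from 5441312 to 9082794 in root tips. Reads were found for 8861 ± 65.3 of the 9433 listed genes in mycelium, 9147 ± 90.1 in fruiting bodies and 7525 ± 91.5 in root tips (mean ± SD, n = 3 each, as throughout). After thinning of every library to the size of the smallest, 8342 ± 33.7 genes in mycelium, 8755 ± 167 in fruiting bodies and 7511 ± 87.6 in root tips still had a read, so every root tip library had reads of fewer genes than any library of the other tissues at equal depth.

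The tissues separated clearly. The first principal component of log2 CPM held 59.2% of the variance and placed fruiting bodies and root tips at its ends, and the second held 28.04% and set mycelium apart from both. Pearson correlations of log2 CPM across the tested genes, which are not independent replicates, were 0.989 to 0.996 between mycelium libraries, 0.95 to 0.96 between root tip libraries and 0.92 to 0.94 between fruiting bodies. Between tissues, r ran from 0.79 to 0.80 for mycelium and root tips, from 0.72 to 0.75 for mycelium and fruiting bodies and from 0.67 to 0.69 for root tips and fruiting bodies. By genes over 4-fold apart, the first of these pairs of tissues (2263 to 2350 genes) lay within the range of the second (1892 to 2615), so their order depended on the measure. The biological coefficient of variation was 0.165 in mycelium, 0.360 in root tips and 0.479 in fruiting bodies. The mycelium libraries came from 1 isolate, whereas each fruiting body was a separate field specimen. Mycelium 1 and 2 were closer to each other, with a chi-square of 32.2 per degree of freedom, than either was to mycelium 3, with 252 and 304. They were counted as 2 samples because the labels call them separate biological replicates; a chi-square does not tell 2 preparations of one culture from separate cultures.

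**Figure D1:**
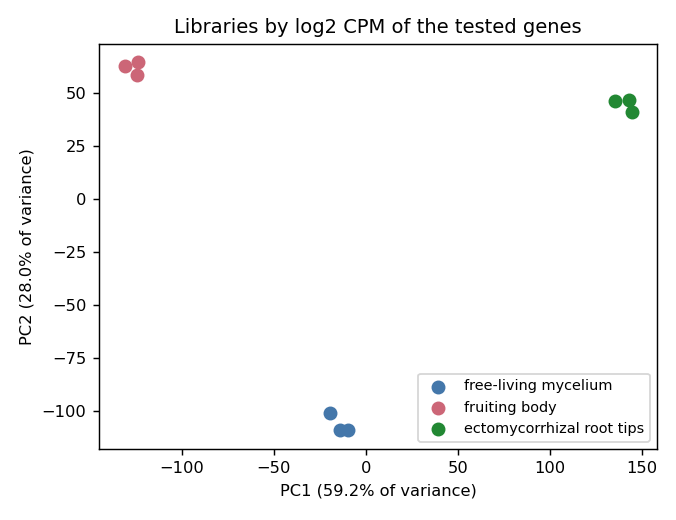
Position of the 9 libraries on the first and second principal components of log2 CPM, 1 point per library and the share of variance on each axis. The 3 libraries of each tissue lie together, and PC1 separates fruiting bodies from root tips.

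A much larger part of the gene reads fell on few genes in fruiting bodies. These are shares of reads without correction for gene length, so they are not shares of RNA molecules. The 20 most abundant genes of each library took 27.2 ± 5.63% of reads in fruiting bodies, against 10.1 ± 0.720% in mycelium and 8.73 ± 0.150% in root tips, and the 3 fruiting bodies lay above all 6 other libraries. For the 100 most abundant genes the shares were 46.3 ± 7.78%, 22.9 ± 0.301% and 21.6 ± 0.301%. With 3 libraries against 3, an exact two-sided permutation test cannot give a p below 0.1. The tissues also filled this abundant class with different genes. Of the 100 most abundant genes, mycelium and fruiting bodies shared 30, mycelium and root tips 24, root tips and fruiting bodies 20, and all 3 tissues 9.

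Among the genes at the top, chosen after their values were seen, gene 308349 (2564 nt) ranked first in mycelium with 1.13 ± 0.326% of reads and first in fruiting bodies with 4.29 ± 2.92%. In the separate fruiting bodies it took 5.28%, 0.999% and 6.58% of reads, so its mean rests on numbers 1 and 3. Gene 335453 (286 nt) took 0.806 ± 0.384% of reads in root tips, with 0.499%, 1.24% and 0.683% in the separate libraries. It had the highest mean there, a rank it lost without root tips 1 (0.959%) or root tips 2 (0.590%). In fruiting bodies it took 0.209%, 4.63% and 2.72% of reads, a mean of 2.52 ± 2.22% that was 1.47% without number 2.

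**Figure D2:**
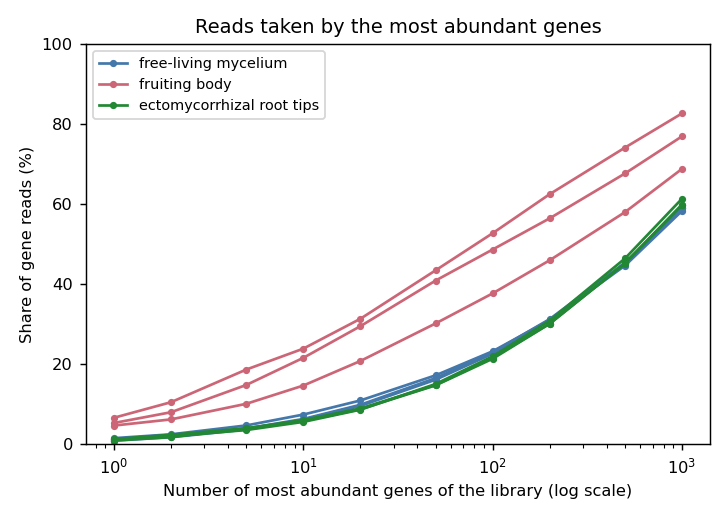
Cumulative share of gene reads (%) taken by the most abundant genes of each library against their number on a log scale, 1 line per library. The 3 fruiting body lines run above the 6 others; at 100 genes they reach between 37.7% and 52.7%, and the others lie between 21.3% and 23.2%.

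The comparison of root tips with free-living mycelium sets the fungus in symbiosis against the fungus alone in liquid culture. Growth conditions and RNA extraction kit differed too, so the differences cannot be credited to symbiosis alone. Of 8695 genes tested, 1370 were higher and 2582 lower in root tips, and 684 and 1384 of these changed at least 4-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The remaining 4743 genes did not pass. Of the lower genes, 491 had no read in any root tip library, so their fitted change is no measure of its size. With such genes at the bound that 3 reads over the tissue allow, 1230 genes were at least 4-fold lower, 108 were at least 64-fold lower and 134 at least 64-fold higher. A fit of only these 2 tissues called 2083 genes higher.

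The increases named by the rule were of genes almost silent in culture. Gene 279135 (509 nt, all reads unique) reached 2297 ± 160 CPM in root tips and 0.135 ± 0.0764 CPM in mycelium, a log2 fold change of 14.03 ± 0.83 (SE; edgeR adjusted p = 1.9e-06). Gene 352248 (1398 nt) reached 728 ± 149 CPM against 0.0595 ± 0.0571 CPM, a log2 fold change of 13.48 ± 0.87 (edgeR adjusted p = 3.0e-06) that was 12.89 without mycelium 1 and 14.47 without mycelium 3. Both also stood far below the root tip level in fruiting bodies, at 1.07 ± 0.650 (0.712 without number 1) and 8.79 ± 4.02 CPM.

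The decreases named by the rule were of genes with no root tip read at all. The rule ranks genes by fitted change, which runs to extremes without reads, so it favours such genes. Gene 308757 (638 nt) had 1075 ± 254 CPM in mycelium and no root tip read, at least 9827-fold lower (edgeR adjusted p = 0.00011). Only 20.4% of its reads were unique, so its level and this bound are shared with other copies. With unique reads alone its fitted log2 fold change moved from -18.30 to -16.12. Gene 348600 (846 nt, all reads unique) had 109 ± 36.03 CPM in mycelium and was at least 950-fold lower in root tips (edgeR adjusted p = 6.1e-06). Without root tips 2, the deepest of these libraries, the reads allowed bounds of 5730-fold and 554-fold.

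Short genes were lower in root tips more often than long genes. In the shortest of 5 length classes of equal size, up to 637 nt, 870 of 1740 genes were lower in root tips and 114 higher, with a median fitted log2 fold change of -1.82, or -1.11 with genes without root tip reads at their bound. In the longest class, above 2016 nt, 250 of 1738 were lower and 397 higher, with a median of 0.16 either way. Fruiting bodies showed no such gradient against mycelium, with medians of 0.35 and 0.16. Once the gradient was taken out of each library, an alternative chosen after the data were seen that also moved the median gene by 0.16 on the log2 scale, 1860 genes were higher and 1626 lower, and the share of higher genes among the calls moved from 34.7% to 53.4%. Settings that left length alone moved it part of the way. It reached 41.9% with median-of-ratios scaling (the same shift of the median) and 43.6% at equal depth. Leaving out any single fruiting body, a tissue outside this comparison, moved it to between 42.5% and 42.8%. The fit of 2 tissues gave 2083 higher and 2546 lower genes. The root tips also differed in RNA extraction kit and depth, and oak reads that matched truffle genes could not be separated here.

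**Figure D3:**
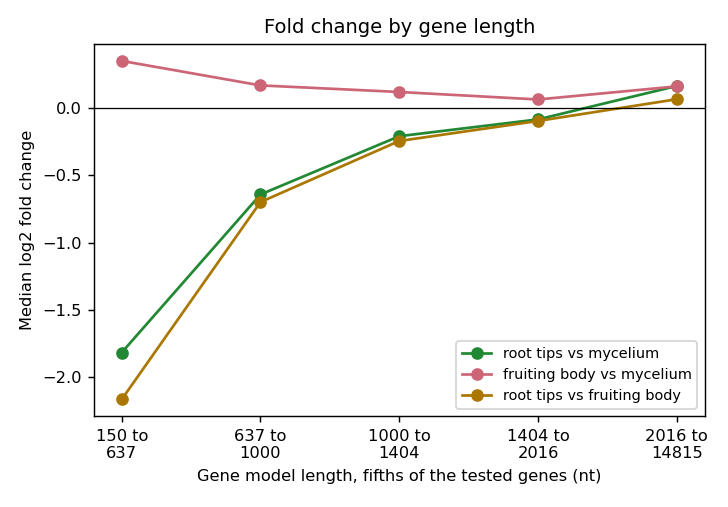
Median fitted log2 fold change of the tested genes (vertical axis) in 5 length classes of equal size (horizontal axis, gene model length in nt), 1 line per comparison. Both lines with root tips rise from the shortest to the longest class, from -1.82 to 0.16 against mycelium and from -2.16 to 0.07 against fruiting bodies, and the fruiting body line stays between 0.06 and 0.35.

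The comparison of fruiting bodies with free-living mycelium sets the sexual stage, as field truffles, against a liquid culture. Growth conditions and origin differed too, so the differences cannot be credited to sexual development alone. Here increases prevailed: 2593 genes were higher and 2050 lower in fruiting bodies, and 1459 and 707 changed at least 4-fold (edgeR adjusted p under 0.05). A further 4052 genes did not pass. With genes that lacked mycelium reads at their bound, 347 genes were at least 64-fold higher, and 23 were at least 64-fold lower.

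Gene 323947 (2055 nt) rose from 0.704 ± 0.208 CPM in mycelium to 6421 ± 2111 CPM in fruiting bodies, a log2 fold change of 13.15 ± 0.76 (edgeR adjusted p = 4.6e-06), and stood at 929 ± 244 CPM in root tips. Gene 329151 (644 nt) had 205 ± 89.9 CPM in fruiting bodies and 4 reads over the 3 mycelium libraries, a log2 fold change of 12.97 ± 0.69 (edgeR adjusted p = 1.1e-05), and no read in root tips. In the other direction, gene 280338 (559 nt) fell from 912 ± 318 to 0.928 ± 0.309 CPM, a log2 fold change of -9.94 ± 0.59 (edgeR adjusted p = 5.9e-06). Gene 344214 (771 nt) fell from 216 ± 52.5 to 0.424 ± 0.109 CPM, a log2 fold change of -8.95 ± 0.38 (edgeR adjusted p = 1.4e-06). Root tips lay between, at 170 ± 63.6 and 16.6 ± 3.45 CPM for these genes.

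The balance of increases and decreases depended on the scaling. With library totals in place of TMM, the median gene shifted by -0.78 on the log2 scale and 1335 genes were higher and 3121 lower, so higher genes made up 30.0% of calls in place of 55.8%. With only the fruiting bodies of 2006, 2425 genes were higher and 1660 lower. The fruiting body of 2005 was a single specimen, so it gives no test on its own.

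The comparison of root tips with fruiting bodies sets the symbiotic against the reproductive state. Of the tested genes 60.5% were called, the highest share of the 3 comparisons in the fit of all tissues: 1881 were higher in root tips and 3377 were higher in fruiting bodies, 769 and 2043 of them at least 4-fold (edgeR adjusted p under 0.05). A further 3437 genes did not pass. In fits of only the 2 tissues compared this comparison had the fewest calls, 1540 higher and 2623 lower, against 2083 and 2546 for root tips and 2633 and 2147 for fruiting bodies against mycelium. Of the genes called lower in root tips, 862 had no read there, and with these at their bound 1975 were at least 4-fold lower. Tested genes without a root tip read were most frequent in the shortest length class (481 of 1740) and rarest in the longest (30 of 1738). Missing reads and the length gradient thus overlapped in part. With such genes at their bound, the median log2 fold change still ran from -1.90 in the shortest class to 0.07 in the longest. Gene 279135 was again first among the genes named by rule, with a log2 fold change of 11.05 ± 0.75 over fruiting bodies (edgeR adjusted p = 5.2e-06), or 11.69 without fruiting body 1. Gene 355669 (1092 nt) had 76.7 ± 44.3 CPM in root tips and 9 reads over the 3 fruiting bodies, a log2 fold change of 10.07 ± 0.88 (edgeR adjusted p = 1.6e-05). This was 11.10 without fruiting body 1 and 9.49 without root tips 2, where the root tip mean fell to 51.1 CPM.

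The decreases named by the rule, which favours such genes, were again of genes without a read in root tips. Gene 308757 was at least 7780-fold lower than in fruiting bodies (1155 ± 1199 CPM, edgeR adjusted p = 8.4e-05), with the limit on unique reads given above. With unique reads alone the fitted log2 fold change of this gene moved from -18.41 to -15.79. Its fruiting body mean fell to 477 CPM without number 3, and the bound was 3981-fold without that library, 12583-fold without fruiting body 2 and 4536-fold without root tips 2. Gene 27630 (219 nt) had 852 ± 769 CPM in fruiting bodies and no read in root tips, where it was at least 6186-fold lower (edgeR adjusted p = 8.7e-05). Without fruiting body 3 its mean was 409 CPM and the bound 3760-fold, and without root tips 2 the bound was 3607-fold. The split of the calls moved with scaling and length here too: higher genes in root tips made up 35.8% of calls, 59.2% with library totals (2831 higher and 1949 lower, median shift 0.80) and 49.2% with the length gradient removed (2402 higher and 2485 lower).

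**Figure D4:**
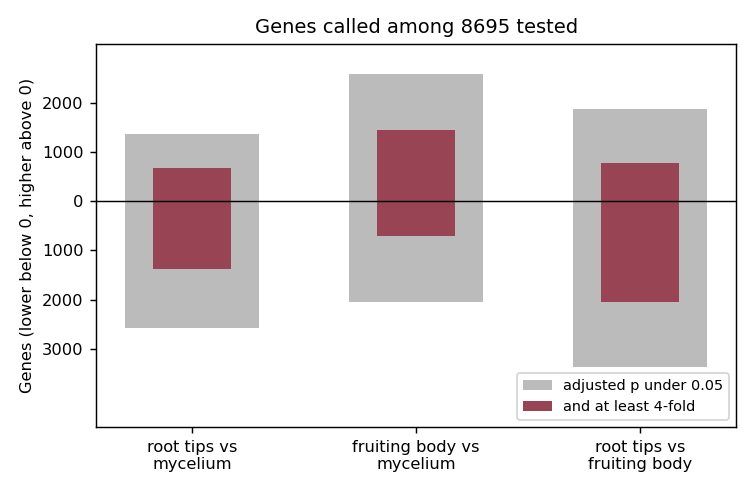
Number of genes called in each comparison among 8695 tested (edgeR adjusted p under 0.05), higher genes above 0 and lower genes below, with genes changed at least 4-fold as narrow bars. Lower genes outnumber higher ones in both comparisons with root tips (2582 against 1370, and 3377 against 1881), a balance that evens out or turns when the length gradient is removed and, against fruiting bodies, turns with scaling by library totals.

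**Figure D5:**
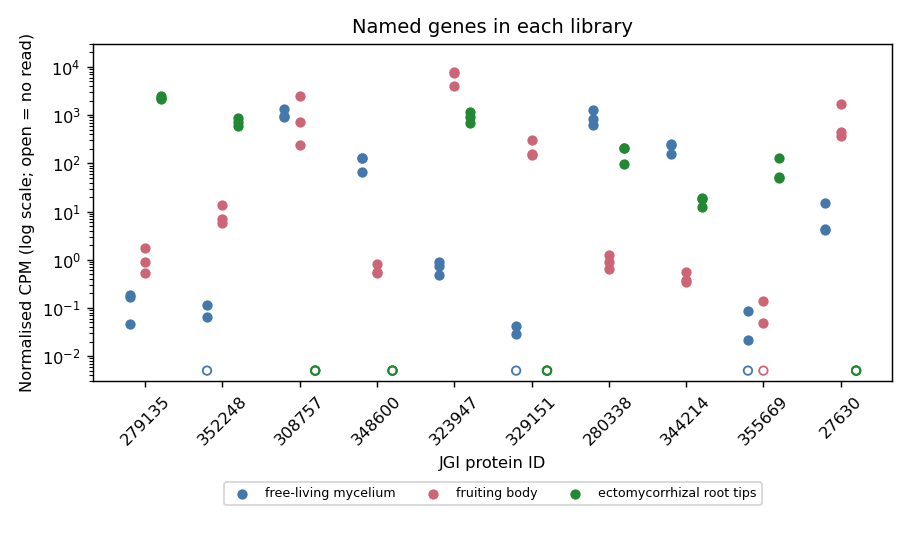
Normalised CPM (log axis) of the 10 named genes in each of the 9 libraries, 1 point per library; open symbols at the bottom mark libraries with no read. In all 3 root tip libraries, genes 308757, 348600, 329151 and 27630 had no read.

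Each tissue had its own set of strongly enriched genes. Fruiting bodies had 1015 genes at least 4-fold higher than in both other tissues, root tips had 369 and mycelium 289. The 1015 fruiting body genes took 47.8 ± 7.34% of fruiting body reads, against 7.38 ± 1.15% in mycelium and 5.54 ± 0.717% in root tips. The 369 root tip genes took 15.8 ± 0.392% of root tip reads, 1.02 ± 0.0376% in mycelium and 0.609 ± 0.212% in fruiting bodies. The 289 mycelium genes took 10.8 ± 0.765% of mycelium reads, 0.552 ± 0.142% in fruiting bodies and 1.04 ± 0.0737% in root tips. These shares describe genes selected for their level in these same libraries. A mean under 1 CPM in both other tissues was found for 563 of 1015 fruiting body genes, 47 of 369 root tip genes and 38 of 289 mycelium genes. The sets differed in level, with a median of 16.3 CPM in their own tissue for fruiting body genes, 119 CPM for root tip genes and 89.4 CPM for mycelium genes, and a gene of low level falls under 1 CPM more easily. At the depth of the smallest library, 648 fruiting body genes met the criterion. With the length trend removed, 914 fruiting body, 515 root tip and 240 mycelium genes met it. With library totals the numbers were 736, 483 and 431. Median lengths were 837, 1395 and 1023 nt in this order, against 1191 nt for all tested genes. The fruiting body and mycelium sets rest on fitted changes, also for genes without root tip reads, and were not counted at the bound. Independent calls would give 343, 60.5 and 113 enriched genes for fruiting bodies, root tips and mycelium, and 20 simulated data sets without any difference gave 0 in each. The simulations leave out real effects, so their 0 does not show how much overlap to expect here. Independence is no strict baseline either, since both contrasts of a tissue depend on its level. Each set rests on 2 contrasts that share 3 libraries, and part of the excess may come from this sharing.

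Calls against mycelium in root tips and in fruiting bodies overlapped in the same direction more often than independent calls would. Genes higher than in mycelium in both root tips and fruiting bodies numbered 652, where independent calls would give 409, and 952 were lower in both, where 609 would be given. Opposite calls were fewer than independent calls would give: 193 genes were higher in root tips and lower in fruiting bodies (323 by independence), and 451 were lower in root tips and higher in fruiting bodies (770 by independence). In simulations without any difference the mean of each overlap was 0, which leaves out real effects and so does not show how much agreement the shared mycelium libraries bring. The covariance of the fold changes across genes was 0.453, against 0.112 in the simulations, where it comes from the shared mycelium libraries alone. The simulations gave every tissue the same spread, a biological coefficient of variation of 0.365 against 0.165 in mycelium itself. The value of 0.112 is thus not the share of the real mycelium libraries, and the difference of 0.342 is no estimate of the covariance beyond it. The correlation across genes was 0.07, against 0.47 in the simulations. Both observed values include the fitted changes of genes without root tip reads, which are no measure of size. With 3 mycelium libraries, no split could keep 2 in each part, and some of the excess overlap may come from them.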

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

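Counts of called genes stayed within 1.5 times their value in 170 of 180 alternative values and in all 99 values with a library left out. Pairwise counts among these 99 came only from leaving out libraries of the 2 tissues compared. With library totals in place of TMM, fruiting body against mycelium gave 1335 genes higher, 3121 lower and 1472 lower at least 4-fold, and root tips against fruiting body gave 2831 higher, 1949 lower and 1414 higher at least 4-fold; the median gene then moved by -0.78 and 0.80 on the log2 scale, and by 0.16 for root tips against mycelium with median-of-ratios factors. Fitting only the 2 tissues compared gave 2083 genes higher in root tips than in mycelium and moved the median gene by 0.15. Leaving out fruiting body 1, 2 or 3, a tissue outside this comparison, also moved it by 0.15. Then 1676, 1829 and 1839 genes were higher in root tips than in mycelium. Median-of-ratios scaling with all fruiting bodies kept gave 1626 higher genes. The balance of these calls thus depended on the scaling as well as on the libraries in the fit. Thinning to the smallest library gave 648 fruiting body genes enriched, with fewer genes tested (7879 against 8695). Removing the length trend, an alternative chosen after seeing the data, gave 1626 genes lower in root tips than in mycelium and 870 lower at least 4-fold; 2863 of the 3952 calls kept their direction and 53 were called in the opposite one. The other settings, DESeq2 among them, moved no count by over 1.5 times. With mycelium 1 and 2 summed as 1 library, also chosen after seeing the data, 994 genes were higher and 2171 lower in root tips than in mycelium. The fold changes of the named genes kept their direction and their call in all 216 alternative values, with adjusted p up to 0.00089 (edgeR and DESeq2). These genes were picked for the largest changes in the same counts, so little else could come out. Their sizes moved more. Against mycelium, the log2 fold change in root tips ran from 13.45 to 15.49 for gene 279135 and from 12.89 to 15.09 for gene 352248. For gene 355669 it ran from 9.49 to 11.83 against fruiting bodies.

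With the replicate number as a replicate block, 1263 genes were higher and 2409 lower in root tips than in mycelium, 2310 and 1952 in fruiting bodies, and 1812 and 3167 in root tips against fruiting bodies. No label says that a number marks a shared origin, and the deviations of same-numbered libraries from their tissue means correlated between -0.07 and 0.08, with the own number giving the best match in 8 of 18 cases, so the numbers were not taken to pair the samples. The planned gene list tests were not run, since the files name no gene products, nor was the pseudocount alternative, which applies only to normalized values. Root tip depth limits what can be said of genes with few reads there.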

Other observations

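A set of genes active in the fruiting body or in mycelium was without reads in the root tips. At 10 CPM or more in every fruiting body, 99 genes had no read in any root tip library, and 22 genes at that level in every mycelium library had none. After thinning of all libraries to one total the numbers were 96 and 22. The 99 genes had a median length of 929 nt, against 1191 nt for all tested genes, so they overlap the length gradient in part. In the other directions at that depth, 10 fruiting body genes and 6 root tip genes lacked mycelium reads, and 0 mycelium genes and 1 root tip gene lacked fruiting body reads. Of the genes without root tip reads, 8 stood at 10 CPM or more in all 6 libraries of the other tissues, gene 308757 among them.

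The tests of the 3 patterns weighed here (genes without root tip reads, few low counts in root tips, and short genes lower in root tips) and the comparison of fruiting body pairs were all chosen after the results were seen; the splits of the samples at the end were planned before the data were examined. Lower read depth argues poorly for the 99 genes, since at one depth 10 fruiting body genes lacked mycelium reads, against 96 that lacked root tip reads. Clumped reads, few RNA molecules each read many times, are a candidate explanation of the low counts of root tips: 98 to 193 genes had 1 to 3 reads after thinning, against 501 to 741 in other libraries, and genes with a mean of 3 to 10 reads in 2 root tip libraries lacked reads in the remaining one in 34.6% of cases (lowest library 27.4%, highest of the other tissues 15.0%). The share was 9.18% at 10 to 30 reads (0.676% in fruiting bodies, 0.192% in mycelium) and 0.594% at 30 to 100 reads (0.0599% and 0%); at their fruiting body level each of the 99 genes would have at least 69.7 reads in every root tip library, which argues against clumping as their whole cause, while a lower level together with clumping stays open. Genes missing from or altered in the truffle strain on the oaks cannot be told apart from silent genes, because no sequence was used here. This holds for the 8 genes and for the others without root tip reads, and a tissue difference stays open.

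Shorter genes were lower in root tips than in mycelium. Few reads of short genes at low depth argue poorly as the whole cause: among genes with a mean of at least 50 CPM the medians of the longest and the shortest class still differed by 1.10 log2 units (95% bootstrap interval over genes 0.97 to 1.26; 308 short and 1307 long genes). Each root tip library showed the gradient, by at least 1.56 log2 units against the mean of mycelium, whereas fruiting bodies lay between -0.33 and -0.13. The RNA extraction kit or library preparation may give such a gradient and cannot be told apart from a tissue difference, because that kit was used for root tips alone.

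Fruiting bodies 2 and 3, from one locality and year, were over 4-fold apart in 781 genes, against 395 for numbers 1 and 2 and 446 for numbers 1 and 3. By chi-square per degree of freedom, numbers 1 and 2 (3396) differed about as much as 2 and 3 (3377), and 1 and 3 less (1786). After thinning the numbers were 809, 426 and 500. The 10 most abundant fruiting body genes took 19.9%, 10.8% and 22.1% of reads in numbers 1, 2 and 3.

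For each of the 3 comparisons, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many calls. The real counts were 3952, 4643 and 5258, or 2068, 2166 and 2812 at least 4-fold, for root tips against mycelium, fruiting body against mycelium and root tips against fruiting body, and the highest other split gave 0 in each. The splits are too few for a share under 0.05. Each other split also mixes both tissues within its groups, which widens the spread, so its 0 is no level to expect without a difference. For enriched genes, 100 splits of the 9 libraries into 3 groups of 3 were compared. As many genes as observed were found in 1 of them for root tips (369, highest other 324), 1 for fruiting bodies (1015, highest other 750) and 3 for mycelium (289, highest other 744). The high counts in other splits point to the structure of the samples: each other split with any such gene kept all 3 libraries of one tissue in the group concerned (2 splits for root tips, 3 for fruiting bodies and 2 for mycelium), and the rest gave 0. These shares thus reflect how few splits keep a tissue whole, and both such splits for mycelium gave more genes than observed, so nothing about chance is concluded from them.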
